A study of Mus musculus with 2 samples.

How the data were processed

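H3K36me3, the trimethylation of lysine 36 of histone H3, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse hindbrain at embryonic day 14.5. The 2 samples were biological replicates of 1 group, each a pool of male and female embryos, per the labels. Replicate 1 was made from 24 embryos and replicate 2 from 34. There was no second tissue, treatment or input library among the samples, so no difference between groups was tested.

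The deposited files were 4 peak lists on mm10. Per the deposited README, the list of each replicate was called on that replicate's alignments against a control alignment of its own, a further list was called on both replicates together, and the replicated list was derived from the other lists. The signal of a peak was the enrichment over control that the authors deposited with it. The −log10 p and −log10 q of a peak were also the authors' deposited values, and −log10 q was used only in the lists of the replicates. The aligner, the peak caller, its version and its threshold were not given in the sources used here. Signal and −log10 p served only to describe, rank or filter peaks within 1 list. The files held no read counts, so the depth of each library was unknown and no interval that needs it was given.

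Peaks were set against the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, on chromosomes 1 to 19, X and Y. Shares of the genome used the 2647568367 bp outside runs of N of 1000 bp or more. Peak bases were assigned in the order within 1 kb of the start of a protein-coding gene, coding exon, 5′ UTR, 3′ UTR, intron, other annotated gene and intergenic. The intron class held every base of a protein-coding gene not in an earlier class. A protein-coding gene was called marked where peaks covered 10% or more of its body in the list of each replicate. Means ± SD were taken over the 2 replicates.

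Peaks counted as shared at 1 bp of overlap. The share was set against 100 placements of the other replicate's peaks at random on the same chromosomes outside runs of N, with a one-sided permutation p whose smallest possible value was 0.0099. Annotation classes were set against 100 such placements with a two-sided permutation p, at best 0.0198. For 31 gene lists, the number of marked members was set against 10000 random lists with as many genes in each of 20 length bins. The two-sided permutation p of these lists, at best 0.0002, was adjusted over the 31 lists by the Benjamini-Hochberg method at 0.05. Fisher's exact test, two-sided, served for 3 comparisons of groups of genes. Exon and intron coverage were compared within genes by a sign-flip permutation test of the mean difference with 100000 flips. Genes are not independent replicates, so all p-values describe these libraries.

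The list test was tested on simulated data with the 21938 genes, where 1% of 100 lists without an effect had a p under 0.05. So did 98% of 100 lists with a large planted effect, 12 of 15 members marked. The simulated share of marked genes rose with length throughout, unlike the real one. No smaller effect and no list marked less often was planted, so the power for those is unknown. Overlaps were checked against bedtools 2.31.1 on simulated intervals. The other steps used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.

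The groups, the tests, the gene lists, the rule for the genes named and most alternatives were fixed before the data were examined. The rule named the 3 members of each list with the highest mean coverage and the lowest member, and every gene in the list of H3K36 methyltransferases. It also named the 15 protein-coding genes of 10 kb or more with the highest coverage. The genes of the 10 longest domains and the genes with the largest difference between replicates were named as well. The alternatives fixed then were −log10 p of 5 or more, −log10 q of 2 or more, other overlap rules and lists with equal numbers of peaks. Random placement within genes only, the replicated list, each replicate alone, and marking at 5%, 25% or 50% were also fixed then. Further ones were lists not matched on length, median coverage as the statistic, a 2 kb window around gene starts, genes of 20 kb or more and other joining distances for domains. Alternatives added later were a circular shift of the peaks, genes that overlap no other coding gene, and the 3′ 50% of the gene. Peaks on unplaced scaffolds entered only the totals of each list.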

Results

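H3K36me3, a histone mark that SETD2 deposits over transcribed gene bodies, was mapped by ChIP-seq in the hindbrain of embryonic day 14.5 mice, the region that forms the cerebellum, pons and medulla. The data were 1 group of 2 replicates, from pools of 24 and 34 embryos, each with a deposited peak list. The depth of the libraries was unknown. The question addressed was where the mark lay in this tissue.

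Called H3K36me3 regions were many and mostly short, and together they took up a small part of the genome. The list of replicate 1 held 173986 peaks with a median width of 375 bp, and the list of replicate 2 held 165870 peaks with a median width of 406 bp. The lists covered 108.8 Mb ± 5.84 (SD, n = 2), or 4.11% ± 0.220 of the sequence outside assembly gaps. The list called on both replicates together held 157181 peaks over 148.7 Mb, and its widest peak spanned 54899 bp. Peaks with −log10 p of 5 or more made up 59.8% of the first list and 63.3% of the second. This threshold lowered the mean number of peaks per list from 169928 to 104455.

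Most peaks of each replicate touched a peak of the other. Of the peaks of replicate 1, 75.4% overlapped a peak of replicate 2, against 8.54% after random placement. In the other direction 71.8% were shared, against 8.87%. Of the bases under a peak in either list, 54.7% lay under a peak in both, against 2.38% by chance. None of the 100 random placements reached any of these values (one-sided permutation p = 0.0099, the smallest possible). With peaks placed at random within genes only, where most peaks lay, the shares by chance were higher, 15.6% and 16.1% of peaks and 4.67% of bases, with the same permutation p. The share also depended on the rule: where 50% of both peaks had to overlap, 32.5% and 34.1% were shared, against 1.41% and 1.46% in 20 placements (one-sided permutation p = 0.0476, the smallest these can give). Sharing at 1 bp followed peak strength: in 10 equal groups by −log10 p, 49.1% of the weakest replicate 1 peaks were shared and 99.4% of the strongest, with 45.6% and 99.3% for replicate 2. Median width also differed between these groups, from 231 to 1317 bp in replicate 1 and from 247 to 1547 bp in replicate 2, and wider peaks meet others more often by chance.

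**Figure D1:**
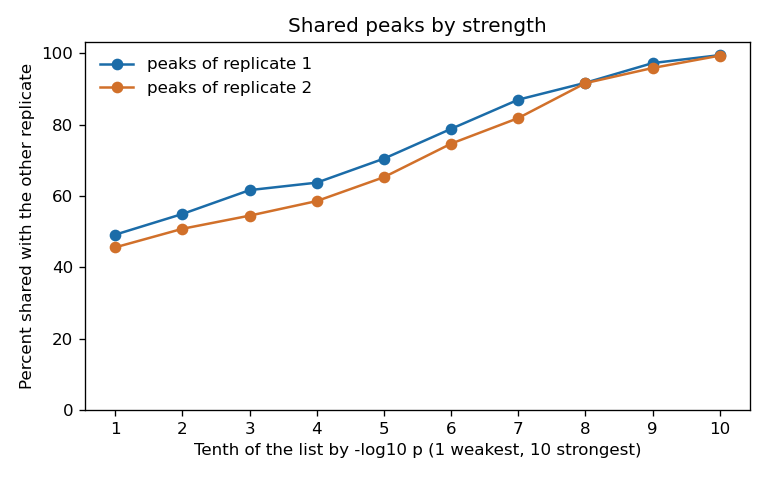
Percent of each replicate's peaks that overlapped a peak of the other replicate (y axis) in 10 equal groups of its own list ordered by −log10 p (x axis, 1 weakest, 10 strongest), with 1 line per replicate. The shared percent went from 49.1 and 45.6 in the weakest group to 99.4 and 99.3 in the strongest.

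The replicated list kept the wider and stronger regions. All of its 91837 peaks on the main chromosomes were rows of the list called on both replicates, and they held 86.3% of that list's bases. Their median width was 807 bp and their median signal 4.06, against 275 bp and 2.73 for the 65326 other peaks. Overlap by 1 peak of each replicate, over 50% of either peak, held for 78641 of the replicated peaks (85.6%) and for 0 of the others. This rule was put first after the values were seen, as it parted the lists best. Of the other 2 rules tried, 1 bp of overlap held for 86.2% of the replicated peaks and 985 of the others, and cover of 50% of the peak itself for 62.7% and 1. The rule that admitted the rest was not given in the sources used here.

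H3K36me3 lay inside genes, most densely over coding exons and 3′ UTRs, and avoided gene starts. Coding exons held 10.5% ± 0.179 of peak bases (SD, n = 2), 7.68 times the share after random placement, and 3′ UTRs held 7.58% ± 0.0113, 5.77 times. Introns held most of the mark, 76.3% ± 0.111 against 38.2% at random. Intergenic sequence held 4.16% ± 0.0395 against 50.5%, and the 1 kb on either side of gene starts held 0.395% against 1.70%. The 5′ UTRs outside these windows stood at 1.27 times and other annotated genes at 0.140 times the random share. Each of the 7 classes lay outside all 100 random placements (two-sided permutation p = 0.0198, the smallest possible).

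**Figure D2:**
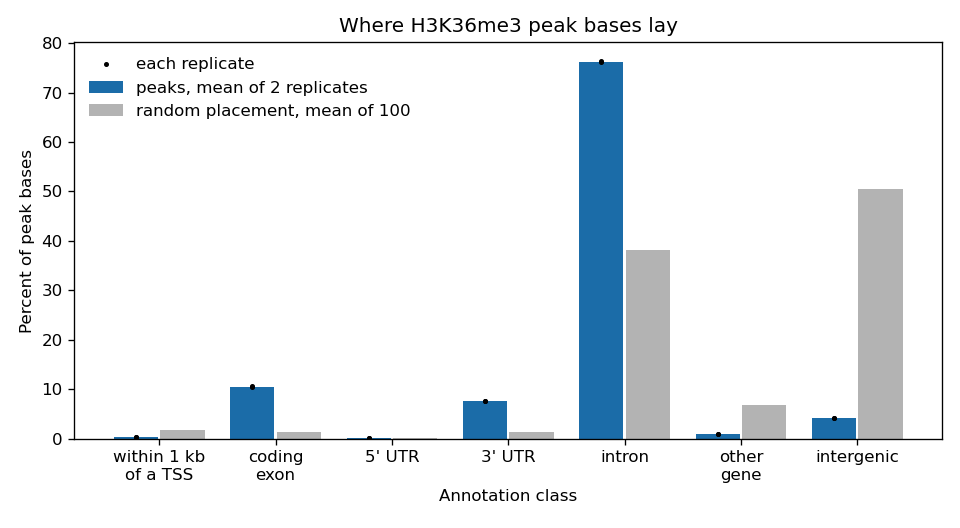
Percent of peak bases (y axis) in 7 annotation classes (x axis), as the mean of the 2 replicates with each replicate as a dot, beside the mean of 100 random placements. Introns, coding exons and 3′ UTRs stood above the random share, at 76.3%, 10.5% and 7.58%, and intergenic sequence below it, at 4.16% against 50.5%.

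Along the gene, coverage built up from the start towards the 3′ end. Over 17798 protein-coding genes of 5 kb or more, peaks covered 0.898% ± 0.0588 of the 1 kb upstream of the gene and 1.11% ± 0.101 of the first of 20 equal parts of the body (SD, n = 2). Coverage was 18.8% ± 0.866 in part 10 and highest in part 19, at 26.7% ± 1.01. It remained at 20.5% ± 1.08 in the first 1 kb past the gene end and was 10.2% ± 0.540 at 5 kb. Upstream of the gene, coverage also rose with distance, to 7.27% ± 0.229 at 5 kb. Neighbouring genes were not excluded from the flanks, so coverage there cannot be assigned to the gene itself. The values were not tested, and both replicates had the same shape.

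**Figure D3:**
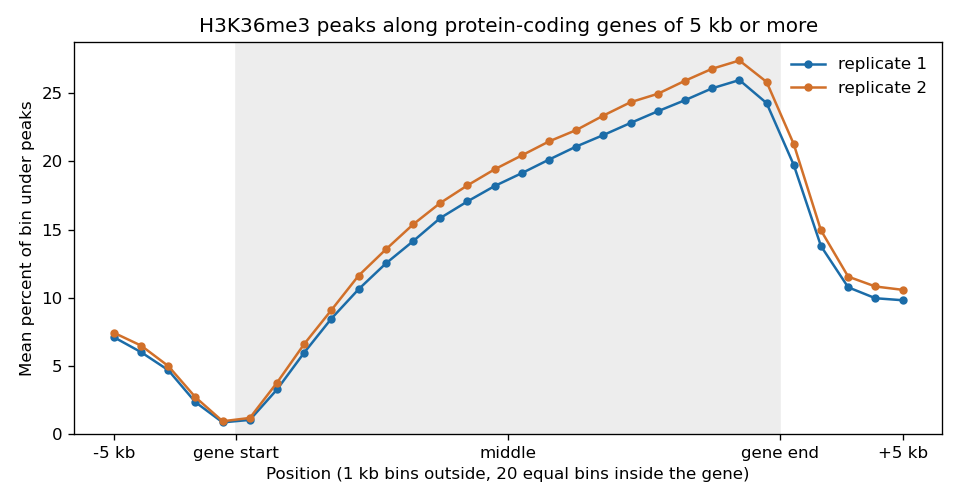
Mean percent of each bin under peaks (y axis) along 17798 protein-coding genes of 5 kb or more (x axis: 1 kb bins outside the gene and 20 equal bins inside it, shaded), with 1 line per replicate. Coverage went from 1.11% in the first part of the body to 26.7% in part 19.

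Peaks covered 10% or more of the body of 7617 of 21938 protein-coding genes (34.7%) in both replicates. The median coverage of these marked genes was 40.6%, with a median SD between replicates of 2.59 points. No peak touched 10273 genes (46.8%) in either list. Intergenic sequence, measured the same way, was covered to 0.320% ± 0.0202 (SD, n = 2). Across genes, which are not independent replicates, the coverage in the replicates had a Pearson's r of 0.984 and a Spearman's rho of 0.969. Another coding gene overlapped 4754 of the genes, and a peak there could not be assigned to 1 of the pair. Of the genes whose coverage is given below, this holds for Alas2, Ash1l, Cnp, Crmp1, Cx3cr1, Ddb1, Eid3, Gm17409, Gm26741, Gm42715, Hist3h2a, Hnf1a, Hoxa2, Ina, Mcm7, Mecp2, Nnat, Nsd2, Phrf1, Psip1, Sf3b3, Smim27, Sycp3, Tubb3 and Uqcrc2. Among genes without such an overlap 30.7% were marked.

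The 15 most completely covered genes of 10 kb or more included several of messenger RNA splicing, though no test was made on this set. Trrap, a scaffold of histone acetyltransferase complexes (chromosome 5, 144767732 to 144859778, mm10), was covered to 91.8% ± 1.41 (SD, n = 2). Rbm5, an RNA-binding regulator of splicing (chromosome 9, 107740371 to 107770996), reached 91.6% ± 1.56 and Kpnb1, an importin (chromosome 11, 97159714 to 97187881), 91.3% ± 2.41. Ddb1, an adaptor of ubiquitin ligases that also acts in DNA repair, was covered to 90.5% ± 0.214. The spliceosome genes Sf3a1 (90.3% ± 0.0191), Sf3b3 (90.2% ± 3.21), Prpf8 (90.2% ± 2.00) and Snrnp200 (88.8% ± 3.03) were among the 15. So were the fatty acid synthase gene Fasn (89.4% ± 0.889), the H3K4 methyltransferase gene Kmt2b (89.0% ± 1.42), Phrf1 (88.8% ± 0.814), Glyr1 (88.6% ± 2.16) and Exosc10, a nuclease of the RNA exosome (88.4% ± 1.35). The other members were 2610507B11Rik (89.6% ± 2.15) and Gm42715 (89.6% ± 3.83).

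Genes that every cell uses and genes of all neurons were marked more often than length-matched genes. Of 84 ribosomal protein genes, 70 were marked against 17.8 in random lists, with Rps15a at 83.7% ± 4.09, Rps3 at 82.4% ± 3.27 and Rps7 at 75.9% ± 0.610, and Rpl41 at 0%. Of 91 annotated genes chosen by symbol for the respiratory chain, 79 were marked against 28.3. The ATP synthase gene Atp5b (79.8% ± 6.84) and Uqcrc2 (78.2% ± 3.01) led this list. Among ubiquitous genes, 19 of 21 were marked against 8.63, with the elongation factor gene Eef2 at 84.4% ± 3.93 and Gusb lowest at 5.45% ± 1.63. Of 24 genes used by all neurons, for the cytoskeleton, adhesion, RNA binding and synapses, 17 were marked against 7.83. Crmp1, which acts in axon guidance, was covered to 53.4% ± 0.911, Tubb3, a neuronal tubulin, to 52.6% ± 2.14, and Ina, a neurofilament gene, to 49.5% ± 5.43, and Rbfox3 was lowest at 0.496% ± 0.377. Crmp1, Tubb3 and Ina each overlap another coding gene, so their peaks cannot be shown to be their own. Each of these 4 lists had a permutation p of 0.0002, the smallest possible, and an adjusted p of 0.000689. The neuronal list lost its call when marking needed 50% coverage (2 of 24 marked, adjusted permutation p = 1).

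Chromatin regulators and zinc finger genes were the other groups marked more often. Of 20 chromatin regulators mutated in neurodevelopmental disorders, 16 were marked against 6.67 at random, with Kmt2d at 83.6% ± 0.715, Smarca4 at 74.2% ± 1.86 and Ep300 at 73.1% ± 2.30, and Mecp2 lowest at 3.60% ± 0.352. Of 394 zinc finger genes, 268 were marked against 163, with Zfp869 at 90.2% ± 6.41 and Zfp606 at 87.5% ± 1.33. Both lists had an adjusted permutation p of 0.000689. Of 20 readers and demethylases of methylated H3K36, 14 were marked against 8.53 (adjusted permutation p = 0.0361). Glyr1 led this list, with the demethylase gene Kdm4a at 87.3% ± 3.56, the reader gene Psip1 at 76.5% ± 5.44 and Phf19 at 0%. The call of this last list was lost in 4 of 9 alternatives, where its adjusted permutation p reached 0.0987.

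**Figure D4:**
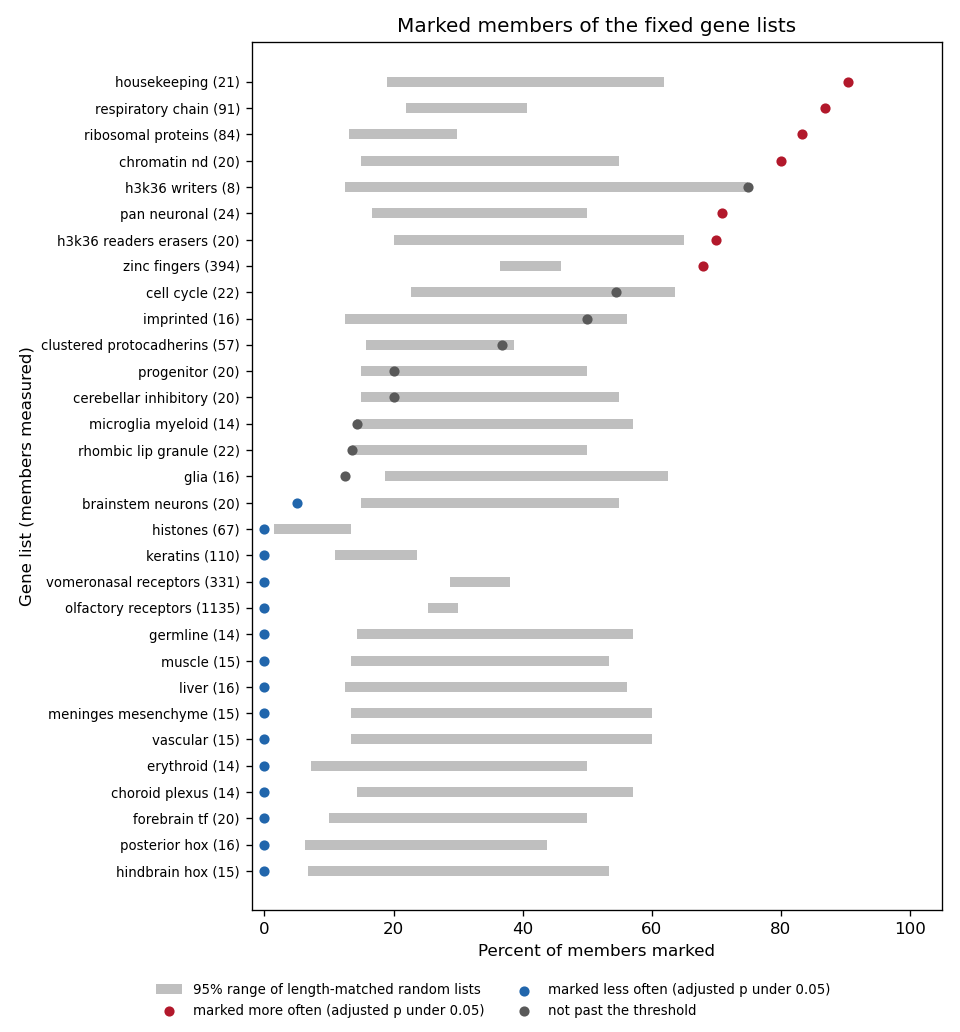
Percent of members marked (x axis) in each of the 31 gene lists (y axis, members measured in brackets), with the 95% range of length-matched random lists as a grey bar. The 7 lists marked more often stood to the right of their bar, from 68.0% to 90.5%, and the 15 marked less often to the left of it, at 0% to 5%.

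Lists of other organs and of other cell types of the head carried almost no called mark. Peaks came from whole tissue, so a mark confined to a minority of its cells may not have been called. Hepatocyte genes had 0 of 16 members marked (adjusted permutation p = 0.00429), with Hnf1a highest at 5.10% ± 1.68. Muscle genes had 0 of 15 (adjusted permutation p = 0.0102), with the titin gene Ttn at 1.22% ± 0.283, and germ cell genes 0 of 14 (adjusted permutation p = 0.00443), with Sycp3 at 2.52% ± 1.41. Endothelial and pericyte genes had 0 of 15 marked (adjusted permutation p = 0.00413), with Pdgfrb at 1.92% ± 0.753. Mesenchyme and meninges genes had 0 of 15 (adjusted permutation p = 0.00225), with the collagen gene Col2a1 at 4.77% ± 3.90. Red blood cell genes had 0 of 14 (adjusted permutation p = 0.0152), with Alas2, which starts haem synthesis, at 7.56% ± 0.161. Choroid plexus genes had 0 of 14 (adjusted permutation p = 0.00581), with Enpp2 at 1.55% ± 0.230 and the transthyretin gene Ttr at 0%. Of 9 alternatives, the call held in 6 for the red blood cell list, in 7 for the choroid plexus, endothelial and muscle lists and in 8 for the other 3, with adjusted permutation p up to 0.555 where it was lost. Each loss came with 0 members marked, the lowest count possible, against fewer expected.

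Large sensory and structural gene families held no marked genes. The aligner was not given, so how reads shared between similar genes were placed was unknown. A lack of peaks in these families may therefore not be a lack of the mark. None of 1135 olfactory receptor genes, 331 vomeronasal receptor genes or 110 keratin genes was marked (adjusted permutation p = 0.000689 for each list). Their highest members were Olfr543 at 1.91% ± 2.70, Vmn2r7 at 0.0726% ± 0.103 and Krt222 at 1.49% ± 2.11. Histone genes, which are short, had 0 of 67 marked against 4.81 at random (adjusted permutation p = 0.0152), with Hist3h2a at 7.04% ± 9.95. The histone call held in 6 of 9 alternatives, and it was lost at 25% and 50% coverage and among genes without overlap (adjusted permutation p = 0.0687, 0.554 and 0.199), each time with 0 marked, the lowest count possible.

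Forebrain transcription factors and genes of brainstem neurons were marked less often than length-matched genes, and 2 lists of cerebellar lineages did not pass the test. Here too, a mark confined to a minority of the cells of the tissue may not have been called. Forebrain transcription factors had 0 of 20 marked against 6.06 at random (adjusted permutation p = 0.00225), with Satb2 highest at 0.0747% ± 0.106. Of 20 genes of brainstem motor, serotonergic, noradrenergic and relay neurons 1 was marked against 7.07 (adjusted permutation p = 0.00455), the glutamate transporter gene Slc17a6 at 20.3% ± 3.92, with Slc6a5 at 6.84% ± 3.35. When marking needed 50% coverage neither list could be called, as 0 marked, the lowest count possible, then gave an adjusted permutation p of 0.515 and 0.4997. The rhombic lip and granule cell list had 3 of 22 marked against 7.12 (adjusted permutation p = 0.0982): the hedgehog receptor gene Ptch1 at 47.6% ± 3.86, Cntn2 at 25.8% ± 0.196 and Meis1 at 22.5% ± 10.6. The Purkinje and GABAergic list had 4 of 20 against 6.68 (adjusted permutation p = 0.293), among them the glutamate decarboxylase genes Gad2 at 28.7% ± 7.54 and Gad1 at 27.4% ± 5.30, and Lhx1 at 27.4% ± 3.21.

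Progenitor, glial, immune and imprinted gene lists did not pass the test. Of 20 progenitor genes 4 were marked (adjusted permutation p = 0.368), with Msi1 at 61.1% ± 0.225, Vim at 48.8% ± 3.50 and Rest at 32.2% ± 1.66. Of 22 cell cycle genes 12 were marked (adjusted permutation p = 0.300), led by the ribonucleotide reductase gene Rrm1 at 69.3% ± 5.71 and the replication genes Mcm4 at 66.5% ± 3.89 and Mcm7 at 65.6% ± 0.388. Oligodendrocyte and astrocyte genes had 2 of 16 marked (adjusted permutation p = 0.0504), Cnp at 69.2% ± 2.36 and Mog at 13.6% ± 0.872. Microglial genes had 2 of 14 (adjusted permutation p = 0.222), Fcer1g at 15.6% ± 4.51 and Cx3cr1 at 15.3% ± 0.256. The imprinted list named 22 genes, of which 16 were measured as protein-coding genes. Imprinted genes so measured had 8 of 16 marked (adjusted permutation p = 0.328), with Nnat at 56.8% ± 16.3, Igf2r at 50.5% ± 5.03 and Peg3 at 47.0% ± 7.93. The noncoding members Mirg, Meg3 and Rian did not enter this test and are described further below. Clustered protocadherin genes, each of which overlaps another coding gene, had 21 of 57 (adjusted permutation p = 0.118). Random lists gave 6.34 marked for progenitor, 9.05 for cell cycle and 6.27 for oligodendrocyte and astrocyte genes. They gave 4.69 for microglial, 5.67 for imprinted and 15.1 for protocadherin genes. A call of marked less often was gained in 5 of 9 alternatives by the oligodendrocyte and astrocyte list. A call of marked more often was gained in 1 of 9 by the cell cycle list and in 2 of 8 by the protocadherin list.

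Most genes in the list of H3K36 methyltransferases were themselves marked. The list was fixed in advance, and whether each of its enzymes acts on H3K36 was not tested. Setd2 was covered to 49.6% ± 4.76 (SD, n = 2). Nsd1 stood at 65.5% ± 4.79, Nsd2 at 52.4% ± 1.82, Ash1l at 47.5% ± 1.80, Nsd3 at 40.5% ± 5.04 and Setd3 at 17.1% ± 1.13. Smyd2 at 6.11% ± 0.942 and Prdm9, a gene of meiosis, at 0.745% ± 1.05 were not marked. With 6 of 8 marked the list did not pass the test (adjusted permutation p = 0.111), and it did with median coverage as the statistic (adjusted permutation p = 0.0132).

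Hox genes, which pattern the hindbrain and the trunk along the body axis, carried little of the called mark. Of the anterior paralogue groups 1 to 5, 0 of 15 genes were marked, and of groups 9 to 13, 0 of 16, so Fisher's exact test gave p = 1. The mean coverage was 2.11% ± 1.51 (SD, n = 2) in the anterior list and 0% in the posterior list. The anterior genes with the highest coverage were Hoxb2 at 10.7% ± 3.26, Hoxa2 at 10.04% ± 14.2 and Hoxb3 at 8.50% ± 3.62. Hoxa2 was covered in replicate 2 only (20.1%, against 0% in replicate 1). In the replicated list 2 of the 15 anterior genes were marked, Hoxb2 at 25.1% and Hoxb3 at 11.5%, and Hoxa2 stood at 0%. Both lists were marked less often than length-matched genes (adjusted permutation p = 0.0141 and 0.0269). With replicate 2 alone 3 of the 15 anterior genes were marked and that list's adjusted permutation p was 0.458. The call was lost in 6 of 9 alternatives for the anterior list, of which 3 had 0 marked, the lowest count possible, and in 4 of 9 for the posterior list, all with 0 marked.

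The hindbrain lists and the forebrain list were compared as groups, which differ in kind of gene. The forebrain list holds only transcription factors. The marked hindbrain genes included the receptor gene Ptch1, the decarboxylase genes Gad1 and Gad2 and the transporter gene Slc17a6. They also included the transcription factor genes Lhx1 (27.4% ± 3.21), Meis1 (22.5% ± 10.6) and Lhx5 (17.7% ± 4.29). The groups were also not matched on length, so the comparison is not one of regional identity alone. Of the 62 genes in the rhombic lip, Purkinje and GABAergic and brainstem lists together, 8 were marked (12.9%), against 0 of 20 forebrain transcription factors. Fisher's exact test did not separate them (p = 0.189). Their mean coverage was 4.73% ± 1.08 and 0.00374% ± 0.00528 (SD, n = 2). Over 7 alternatives the exact p lay between 0.0577 and 1.

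The X chromosome carried much less of the mark than the autosomes. Of 948 X-linked protein-coding genes 127 were marked (13.4%), against 7490 of 20807 autosomal genes (-22.6 points; Fisher's exact test, p = 4.99e-53). Peaks covered 0.797% ± 0.0716 of the X (SD, n = 2). Among the autosomes, coverage ranged from 2.97% ± 0.184 on chromosome 3 to 7.55% ± 0.429 on chromosome 11. The Y chromosome, with 0 of 183 genes marked, was covered to 0.00832% ± 0.00303. Embryos of both sexes were pooled, so the values are those of the pool.

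**Figure D5:**
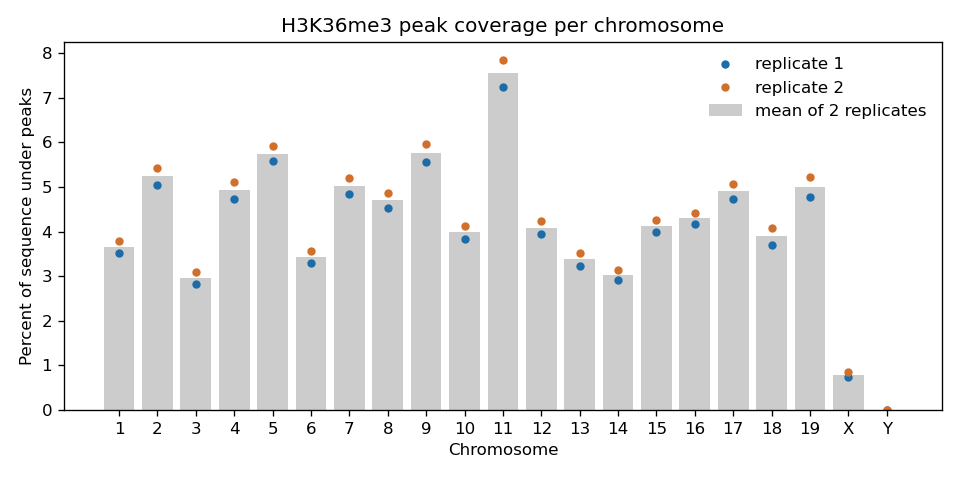
Percent of gap-free sequence under peaks (y axis) on each chromosome (x axis), as the mean of the 2 replicates (bar) with each replicate as a dot. The X stood at 0.797% and the autosomes between 2.97% and 7.55%.

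Within marked genes, exons were more covered than introns. Over 7299 marked genes with 3 or more exons, the median coverage was 59.4% of exon bases and 37.1% of intron bases. The median difference within genes was 17.7 points in replicate 1 and 17.8 points in replicate 2. Exons were the more covered part in 5924 genes and introns in 1373. The mean difference within genes was 17.8 points (sign-flip permutation p = 1e-05, the smallest possible). In the 3′ 50% of the gene alone, an alternative added later, the median difference was 10.05 points.

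Genes of middling length were marked most often. Protein-coding genes were put in 10 equal groups by length. Of the shortest group, with a median length of 1.41 kb, 8.71% were marked. The percent marked was highest, at 48.8%, in group 7, with a median length of 29.9 kb. It was 18.6% in the longest group, whose median length was 186 kb. Across genes, which are not independent replicates, Spearman's rho of length and coverage was 0.238.

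The longest domains of joined peaks lay over single very long genes or short runs of neighbours. Replicated peaks within 3 kb of each other formed 18914 domains, of which 23 were 100 kb or longer. The longest, 153.7 kb on chromosome 4 (145037124 to 145190828, mm10), lay over Vps13d, a gene of lipid transport between organelles. Domains of 152.9 kb over the ubiquitin ligase gene Herc2 (chromosome 7, 56081911 to 56234856) and of 152.0 kb over Usp34 and Ahsa2 (chromosome 11, 23344056 to 23496024) followed. The others of the 10 longest lay over a part of Fry (132.0 kb), which was less than 50% of the gene, and over Wdfy3 (131.5 kb), Mtor with Exosc10 and Angptl7 (131.4 kb), Hectd4 with Trafd1 (130.0 kb), Herc1 with less than 50% of Fbxl22 (128.2 kb), Ncor1 with Ttc19 (126.9 kb) and Birc6 (115.9 kb). Peaks of the replicates covered 73.3% ± 0.547 (SD, n = 2) of the Vps13d domain and 85.1% ± 1.18 of the Hectd4 domain. The Usp34 domain was covered to 60.5% ± 1.71, so the domains held gaps. Joining within 1 kb or 10 kb kept only 3 or 2 of these 10 domains among the longest.

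Few genes were marked in 1 replicate and bare in the other. There were 36 such genes in replicate 1 and 68 in replicate 2, with less than 2% covered in the other list. They were short, with median lengths of 2.85 kb and 3.05 kb against 17.4 kb for all genes. The largest differences were at Gm9803 (55.4% in replicate 1), Smim27 (40.3%) and Hspb9 (35.0%), each at 0% in replicate 2. In the other direction they were at Gm26741 (100%), Eid3 (53.1%) and Gm17409 (34.8%), each at 0% in replicate 1. Lists cut to the same number of peaks, 165855 each, gave 31 and 78 genes. The bases covered were not made equal: the full list of replicate 2 covered 113.0 Mb and that of replicate 1 104.7 Mb. Among the 7617 marked genes, coverage was higher in replicate 2 for 5509 and in replicate 1 for 2093.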

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

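Peaks on unplaced scaffolds lay outside every comparison above and were seen in both lists. The list of replicate 1 held 13 such peaks and that of replicate 2 held 15. The scaffolds GL456216, placed on chromosome 4, and GL456233, placed on the X, held 4 and 8 of them in replicate 1, and 4 and 9 in replicate 2. No gene annotation was used for these sequences and no control sample was at hand, so no explanation was weighed.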

How the results depend on the processing

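Alternatives added after seeing the data were the circular shift, the genes without overlap and the 3′ 50% of the gene. Of 129 values for the comparisons under alternatives, 117 stayed the same (same call, within the replicate SD, or within 1.5 times the count) and 12 moved. Requiring −log10 p of 5 or more left 104455 peaks and 88.0 Mb per list, with a median width of 554 bp. Requiring −log10 q of 2 or more left 102.0 Mb and a median width of 434.5 bp. Both follow from the removal of weak, narrow peaks. With 50% of the replicated peak covered in both lists, 62.7% met the overlap rule. At 50% coverage 2387 genes were marked. The number of lists marked less often was 15, and it went to 8 when marking needed 25% coverage, to 3 at 50% and to 0 with median coverage as the statistic. Each list that lost its call there had 0 marked or a median of 0, the lowest value possible, so these falls come from random values too low to lie above it often enough, and show nothing about stability. The longest domain was 121.5 kb when joined within 1 kb and 231.6 kb within 10 kb. Of 309 values for single lists, 253 kept their call, 47 lost it and 9 gained one. The glia list gained a call in 5 alternatives, each time as marked less often. Housekeeping, chromatin regulator, ribosomal protein, respiratory chain and zinc finger genes kept theirs in all 9 alternatives of the marked count. Of 284 values for named genes with other peaks, 120 moved by more than the replicate SD. Leaving out 1 of 2 replicates cannot move a mean by more than its SD, so for values without a test it shows nothing about stability. The covered bases and the median width without 1 replicate were thus bound to be labelled the same, and add nothing to the count of unchanged values above. Reciprocal overlap of 50%, run with 20 placements, lowered the shared peaks to 32.5% and 34.1%. Depth was unknown, so its part in the weak peaks was not tested.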

Other observations

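The gene families, noncoding genes and strongest peaks here were chosen after the data were seen, and the test in the 3′ 50% of genes was chosen after its result was seen. Gene families defined by gene symbol were tested as 16 lists in the same length-matched way, and 6 were marked more often. Of 71 splicing factor genes 67 were marked against 27.9 at random, of 34 aminoacyl-tRNA synthetase genes 30 against 14.5, and of 21 nucleoporin genes 19 against 9.43. Proteasome subunit genes (39 of 50), Mediator subunit genes (24 of 30) and ubiquitin-specific protease genes (39 of 56) were also marked more often. Marked less often were 7 families. Potassium channel genes had 5 of 81 marked against 26.9, GABA and glutamate receptor genes 3 of 46 against 12.5, Wnt and Fgf ligand genes 2 of 41 against 15.1, collagen genes 0 of 44, cytokine and chemokine genes 1 of 86, cytochrome P450 genes 2 of 80 against 34.9 and defensin genes 0 of 64 against 10.1. The adjusted permutation p of these lists was at most 0.000738. Sodium and calcium channel genes (7 of 20, adjusted permutation p = 0.793), axon guidance genes (24 of 62, 0.287) and kinesin genes (17 of 39, 0.756) did not pass the test, though the axonal motor gene Kif1a was covered to 71.9% ± 0.857 and the calcium channel gene Cacna1b to 48.2% ± 3.09 (SD, n = 2).

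Among noncoding genes of 10 kb or more outside coding genes, the maternally expressed RNAs of the imprinted Dlk1-Meg3 cluster on chromosome 12 held 3 of the 4 highest values. Mirg was covered to 70.9% ± 7.71, Meg3 to 67.0% ± 8.45 and Rian to 53.3% ± 8.54 (SD, n = 2), with 1700020I14Rik between them at 56.6% ± 3.29. D930016D06Rik (51.7% ± 7.14) and Gm3764 (46.3% ± 4.19) came next. Known neural RNAs picked from further down the order were Miat at 40.1% ± 1.97, Rmst at 39.6% ± 7.54 and the microRNA host genes Mir9-3hg at 31.2% ± 5.54 and Mir124-2hg at 14.9% ± 3.70. Of 5358 lincRNA genes outside coding genes, 67 were marked (1.25%).

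The X chromosome had fewer marked genes, and the tests argued against gene length and gene content as the whole cause. Autosomal genes of the same lengths would give 32.1% marked, against 13.4% on the X (permutation p = 0.0002). In 7 lists of broadly used genes 5 of 12 X-linked members were marked, against 210 of 253 autosomal members, and their mean coverage differed by -31.2 points within lists (permutation p = 2e-05). X peaks had a lower median signal, 3.34 and 3.42 in the lists of the replicates (mean 3.38), than any of the 19 autosomes, whose lowest medians were 3.64 and 3.70. A weaker signal from the X, as 1 active copy per cell could give, remains a candidate explanation, and apart from gene content no biological explanation was tested, because the design has 1 group.

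Zinc finger genes lay under 13 of the 20 and 96 of the 1000 strongest replicated peaks by −log10 p, and under 2.06% of all of them. Only 4 of these 13 and 23 of these 96 peaks, but 878 of all 1891, lay over genes with no other zinc finger gene within 500 kb, so shared reads remain open as a cause of the strongest peaks. Zinc finger genes were found by gene symbol, so a neighbour with another kind of symbol could be missed. By that definition 80 of 121 with no other zinc finger gene within 500 kb (66.1%) were marked, against 38.1% of length-matched genes (permutation p = 0.0002). Reads shared between neighbours so defined are thus not the whole cause of the frequent marking. Lists matched on GC content gave 34.8% marked, against the 68.0% observed, which argues against GC content of the gene as the whole cause. Reads shared between distant copies, or with neighbours of other symbols, were not tested, and no biological explanation was tested.

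The higher coverage of exons was tested against 3 technical trends, each taken alone. It was 10.05 points in the 3′ 50% of genes, smaller than the 17.7 points over whole genes. Over all genes of 5 kb or more, coverage still rose within that part, from 19.8% in part 11 to 26.7% in part 19. Position along the gene was thus not removed, and this test cannot tell whether it is the whole cause. Over bases outside repeats the median difference was 16.3 points. In the 591 genes whose exons were no richer in GC than their introns it was 15.1 points (sign-flip permutation p = 1e-05 for the mean difference in each). These values argue against repeats or GC content as the whole cause. The trends were not tested together, and no biological explanation was tested.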
